A study of Mus musculus with 6 samples.

How the data were processed

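Gene expression was measured by RNA sequencing in 6 samples. Per the labels' protocols, 1.3 ug of Trizol-extracted RNA per sample went into a directional library kit (NEBNext Ultra II). The samples were primary mouse lung ILC2 cultured for 24 h with interleukins 2, 7 and 33 at 10 ng/ml and an IgG2b isotype antibody (3 samples) or DTA-1 (3 samples). Groups and replicate numbers were taken from the sample titles. The treatment tags of replicates 2 and 3 name antibodies with running numbers (IgG3b, IgG4b, DTA-2, DTA-3), which disagree with the titles and were not used.

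The authors deposited 1 table per sample with a gene symbol and 1 value per gene, 23183 genes in each. The labels and file headers do not name the unit. The values of the deposited tables were taken as FPKM, because they are not whole numbers, sum to between 574195 and 606724 per sample, and rise at low levels in steps that scale with the inverse of transcript length. Reads were aligned with TopHat to mm10, per the submitters' processing notes. The aligner's version, the program that computed the values, its annotation, its use of strand and the read length are not given in the sources used here. Overlapping and antisense genes, and near-identical paralogs such as histone genes, therefore carry an uncertain share of their reads. The comparison was planned for counts, with limma on the log scale as the planned choice for normalized values. Because the values are not counts, limma was used, and the negative binomial tests, voom and the filter on counts were not run.

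The depth per sample was estimated from the smallest steps between low values, multiplied by transcript length, which gave 18800000 to 20600000 fragments. Lengths, GC content and coordinates came from GENCODE release M21 on GRCm38, the assembly of mm10, and 98.4% of the listed genes had a length. Differences between libraries of a group were 5.26 to 41.2 times the counting noise at that depth, so no library was treated as a copy of another. An exact 0 can be a failed estimate in such files: 37 genes were at 0 in at least 1 library and at 5 FPKM or more in another, and 29 of these had small RNA names. Such genes are given as listed at 0, without a fold change. No gene of the mitochondrial genome was in the tables used here, so that list gives no value.

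Genes with at least 1 FPKM in at least 3 libraries (10501) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (trend and robust), group as the single term, 2-sided tests and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. A fold change on this scale understates the change of low genes. The 41 gene lists (26 pathways, 12 other cell types and 3 signs of RNA quality, with 908 of 945 genes in the files) were fixed before the data were examined. Lists with at least 5 tested genes (27) were tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list. The adjusted p of list members was computed over all genes and over each list alone, the latter without correction for the number of lists. Several genes belong to more than 1 list, among them Tnf, Lta, Traf1, Stat5a, Atf3, Bcl2l1, Birc3, Cflar and Myc, and can pass in one list alone and not in another.

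The genes named in the text were chosen by a rule written before the data were examined. It takes Tnfrsf18; up to 12 genes per direction past the threshold with a mean of at least 5 FPKM and no overlap between groups; 24 fixed genes of ILC2 and GITR biology; up to 4 members per pathway list past the threshold or otherwise the 2 with the smallest p; and the most abundant member of each other list. Further list members named as examples of a count adjusted over the list alone, and single library values, were chosen after their values were seen.

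The procedure was tested on simulated data for this comparison, with 200 of 10501 genes changed by set folds and a further list of genes raised. The noise was independent and normal, with each gene's moderated variance from the fit. It recovered 36.6% of the genes changed by 1.5-fold, 92.5% of those changed 2-fold and 99.7% of those changed 4-fold. Over 10 rounds, 6.07% of calls were false on average, with calls of the raised list not counted as false. Genes of the real libraries vary together, which the simulation did not include. Moderated variances also lie closer together than the real spread, so these shares may be too high for the real libraries. There Il9 and Csf2 did not pass over all genes, with log2 fold changes of 3.46 and 2.73. Alternatives covered the pseudocount, the filter, scaling between libraries, the threshold, blocks, leaving out libraries, the removal of trends with GC content and length (a smooth fit with mgcv 1.9.3) and library quality weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.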

Results

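RNA was sequenced from group 2 innate lymphoid cells (ILC2) of the mouse lung, lymphocytes without antigen receptors that secrete type 2 cytokines. The cells were kept for 24 h with interleukins 2, 7 and 33 at 10 ng/ml and either DTA-1, an agonist antibody against the TNF receptor family member GITR, or an IgG2b isotype control antibody. There were 3 libraries per group. Each library listed 23183 genes in values taken as FPKM, with totals between 574195 and 606724 FPKM and between 14586 and 14939 genes above 0. The steps between low values corresponded to between 18800000 and 20600000 fragments per library, so depth differed little between libraries. Because the labels do not say whether the libraries came from separate animals or cultures, the p-values measure the spread between these samples, which may be technical. The comparison addressed how GITR engagement alters the transcripts of cytokine-activated ILC2. Values are means ± SD in FPKM with n = 3 per group, and log2 fold changes are on the log2(FPKM + 1) scale with the SE of the fit.

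Transcripts of several effector cytokines of ILC2 were higher with DTA-1, though none passed the threshold over all genes. Il9, which encodes a growth factor for mast cells and ILC2, rose from 411 ± 165 to 4814 ± 3130 FPKM, a log2 fold change of 3.46 ± 0.45. Csf2, which encodes GM-CSF, rose from 66.4 ± 12.4 to 487 ± 280.0 FPKM, and Il13, which drives mucus production, rose from 2326 ± 453 to 5422 ± 720.0 FPKM, with log2 fold changes of 2.73 ± 0.34 and 1.23 ± 0.16. Of the 19 tested members of the fixed list of type 2 and other effector cytokines, 8 rose and 1 fell in the limma test adjusted over the list alone. The other risers were Il6, from 7.80 ± 3.73 to 30.6 ± 15.5 FPKM, Tnf, from 28.5 ± 2.44 to 57.7 ± 14.5 FPKM, Lta, Penk and Csf1. Lif, a cytokine of the interleukin 6 family, fell from 68.2 ± 22.9 to 25.9 ± 1.58 FPKM.

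Other cytokines with a central place in ILC2 biology did not pass the test. Il5, the eosinophil growth factor, measured 2169 ± 531 FPKM with the isotype and 3183 ± 747 with DTA-1. Il4 stood at 11.2 ± 2.80 and 10.0 ± 0.508 FPKM. The tissue repair factor Areg measured 130.4 ± 10.2 and 94.9 ± 46.5 FPKM, and Il10 122.8 ± 64.4 and 47.7 ± 38.4 FPKM. In DTA-1 replicate 1, Il10 and Areg lay at 3.45 and 41.3 FPKM, against 66.3 and 121 FPKM in DTA-1 replicate 2. The same library had the highest Il9, at 8425 FPKM against 3151 and 2868 FPKM in DTA-1 replicates 2 and 3. Ifng, the signature cytokine of type 1 lymphocytes, was near the floor at 0.287 ± 0.0754 and 0.283 ± 0.290 FPKM and was not tested.

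The cytokine list as a whole moved up against the other genes by limma's camera (adjusted p = 0.0106; adjusted p = 0.299 with an estimated correlation), although its median log2 fold change was only 0.11. With each library left out in turn, 7 or 8 members rose, and 2 fell without DTA-1 replicate 2. The list median was 0.28 without DTA-1 replicate 2, 0.20 without isotype replicate 1 and 0.067 without isotype replicate 2. The camera call of the list was lost once the trend of each library with GC content and transcript length was removed, with a list median of 0.14. Over all 10501 genes tested, the limma adjusted p was 0.0648 for Il9, 0.0641 for Csf2 and 0.0663 for Il13, so none of these passed, with DTA-1 values above every isotype value for each gene. On chromosome 11 of GRCm38 (mm10), GENCODE places Il4 at 53602982 to 53618669, Il13 at 53631324 to 53634702, Il5 at 53720794 to 53725106 and Csf2 at 54247271 to 54249667. Il9 lies apart on chromosome 13, at 56479277 to 56482246. The tables give 1 value per gene, so isoforms are not told apart.

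**Figure D1:**
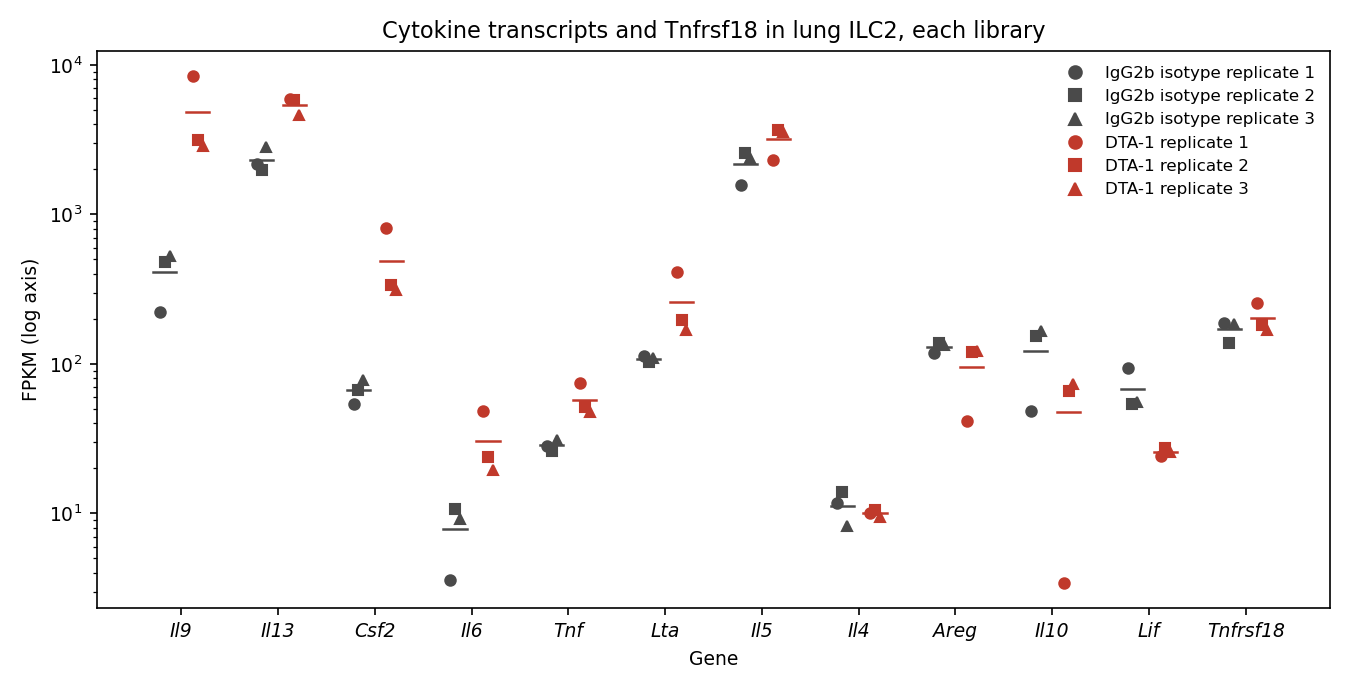
FPKM of 11 cytokine genes and of Tnfrsf18 in each of the 6 libraries on a log axis; points are libraries (grey, IgG2b isotype; red, DTA-1; the marker shape is the replicate) and bars are group means. Il9, Il13 and Csf2 lie higher in each DTA-1 library than in any isotype library, whereas the Il5, Il4 and Tnfrsf18 values of the groups overlap.

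Tnfrsf18, the gene of GITR itself (chromosome 4, 156026164 to 156028895), was expressed in both groups, at 170 ± 27.8 FPKM with the isotype and 203 ± 46.8 with DTA-1 (log2 fold change 0.24 ± 0.19, limma adjusted p = 0.649). Among the 25 tested members of the TNF receptor family and its adaptors, 8 rose and none fell adjusted over the list alone. Tnfsf4, which encodes the OX40 ligand, rose from 48.0 ± 11.3 to 103 ± 14.3 FPKM, and Cd70, the ligand of CD27, from 11.8 ± 3.32 to 24.2 ± 3.86 FPKM. Tnf, Lta, Traf1, Traf6, Tnfsf8 and Tnfrsf25 were the others. The receptors Tnfrsf4 (18.1 ± 8.85 and 37.8 ± 21.9 FPKM) and Tnfrsf9 (17.0 ± 5.73 and 25.1 ± 4.55 FPKM) did not pass.

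Genes of the NF-kB pathway, the main transcriptional route of TNF receptors, rose in 18 of 42 tested cases and fell in none, adjusted over the list alone. Nfkb2, a subunit gene of the non-canonical branch, rose from 65.2 ± 13.1 to 132 ± 32.8 FPKM, and the inhibitor gene Nfkbia from 189 ± 20.3 to 272 ± 51.0 FPKM. The survival gene Bcl2l1 rose from 61.2 ± 17.7 to 107 ± 6.38 FPKM, the adaptor gene Traf1 from 77.9 ± 10.3 to 124 ± 9.58 FPKM, and the surface marker gene Cd83 from 1.46 ± 0.571 to 9.86 ± 4.15 FPKM. Relb, Birc3, Rel, Tnip1, Icam1 and Tnfaip3 also rose. Bcl2l1, Birc3 and Cflar passed in this list but not in the list of apoptosis and survival genes (adjusted p = 0.0612, 0.0908 and 0.129 over that list alone). Nfkb1, at 149 ± 9.88 and 169.9 ± 35.8 FPKM, did not pass. Immediate early, AP-1 and NFAT target genes included 6 members that rose and 1 that fell among 32 tested: Atf3, Egr1, Myc, Klf4, Dusp4 and Ier5 rose and Batf fell. Egr1, for example, rose from 4.86 ± 0.568 to 10.2 ± 1.98 FPKM, while Batf fell from 246 ± 35.9 to 179.7 ± 8.27 FPKM.

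By camera, the lists of NF-kB genes (median log2 fold change 0.44, adjusted p = 1.2e-11; adjusted p = 0.299 with an estimated correlation), TNF receptor genes (0.36, adjusted p = 3.2e-05; adjusted p = 0.360 with an estimated correlation) and immediate early genes (0.29, adjusted p = 4.7e-04; adjusted p = 0.299 with an estimated correlation) lay higher with DTA-1. The list means of DTA-1 replicate 1 stood above those of the other DTA-1 libraries, with TNF receptor genes 0.47 above the mean of all libraries on the log2 scale against 0.13 and 0.03, and NF-kB genes 0.35 above it against 0.15 and 0.12. Without DTA-1 replicate 1, 8 NF-kB genes and 3 immediate early genes rose. The TNF receptor count was 5 without isotype replicate 2 and 4 without isotype replicate 3, and the immediate early count was 2 without isotype replicate 1, 4 without isotype replicate 2, 3 without DTA-1 replicate 2 and 4 without DTA-1 replicate 3. A member of that list fell again only without isotype replicate 2. Without isotype replicate 2, 1 NF-kB gene and 1 TNF receptor gene fell.

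**Figure D2:**
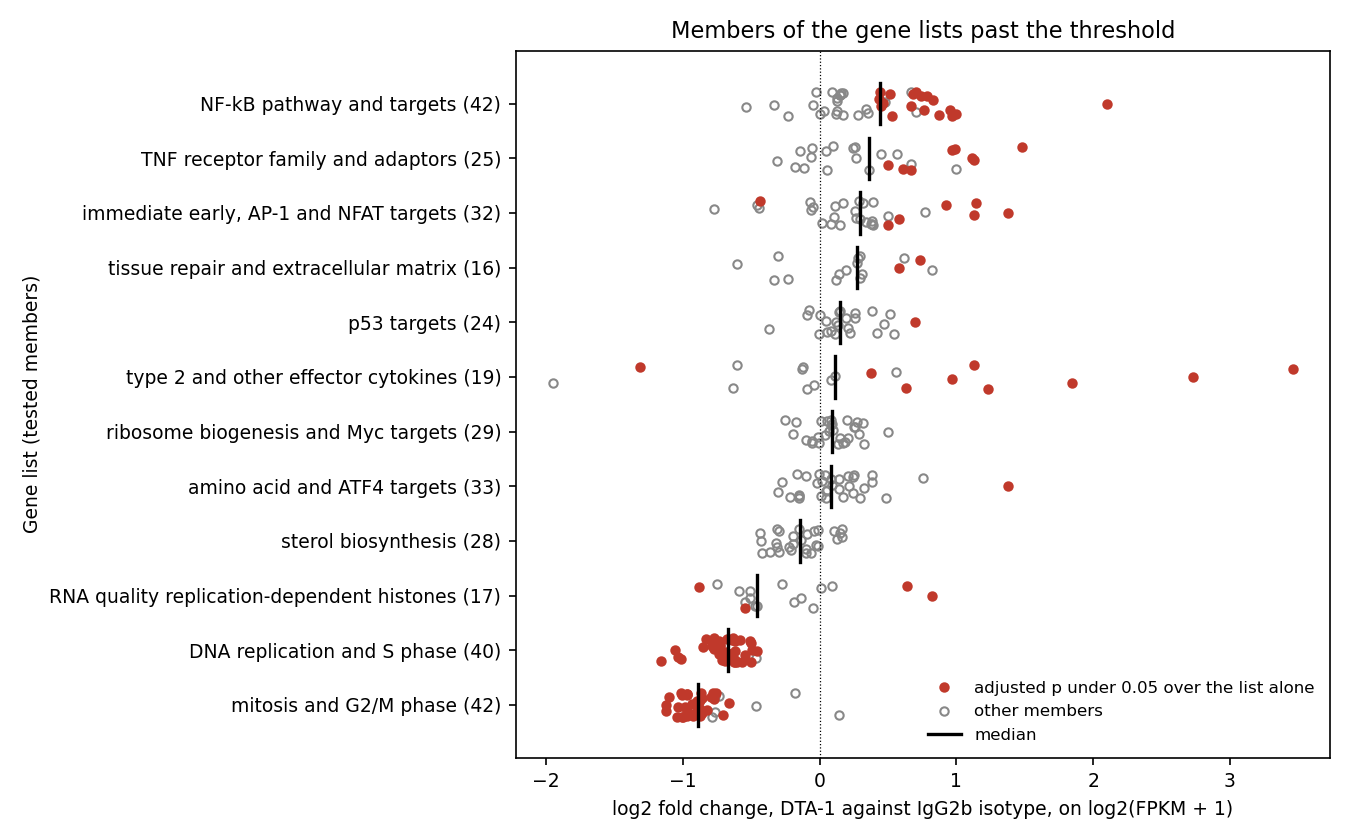
Log2 fold change of each tested member of the 12 gene lists that passed the camera test with a preset correlation, on the log2(FPKM + 1) scale; each circle is a gene, filled red where the adjusted p over the list alone was under 0.05, and the black bar is the list median. S phase and mitosis genes lie almost entirely below 0, with medians of -0.67 and -0.89, and NF-kB genes lie mostly above 0, with a median of 0.44. None of the 12 lists passed with an estimated correlation.

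Proliferation genes were lower with DTA-1. Of 40 tested genes of DNA replication and S phase, 39 fell adjusted over the list alone. Pcna, the sliding clamp of DNA polymerases, fell from 301 ± 36.5 to 180.2 ± 6.07 FPKM, and the helicase subunit gene Mcm5 from 83.0 ± 17.1 to 48.9 ± 1.34 FPKM. Of 42 tested genes of mitosis and the G2/M phase, 35 fell. The proliferation marker Mki67 fell from 71.0 ± 38.5 to 32.4 ± 6.44 FPKM, the kinetochore gene Ndc80 from 18.6 ± 5.51 to 7.75 ± 0.706 FPKM, and the chromatin protein gene Hmgb2 from 193 ± 60.2 to 86.6 ± 6.64 FPKM. The list medians were -0.67 and -0.89 on the log2 scale, and both lists lay lower by camera (adjusted p = 2.9e-33 and 1.2e-22; adjusted p = 0.299 and 0.362 with an estimated correlation). The estimated correlations between members were 0.71 and 0.88, so the counts of genes that fell are not counts of separate results. Cdkn1a, the cyclin-dependent kinase inhibitor gene in the list of p53 targets, rose adjusted over the list alone, from 339 ± 27.8 to 554 ± 97.6 FPKM.

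Isotype replicate 1 had the highest cell-cycle levels. Its mitosis genes lay 1.09 above the mean of all libraries on the log2 scale, against 0.16 and 0.03 in isotype replicates 2 and 3 and -0.22, -0.58 and -0.48 in the DTA-1 libraries. Without it the list medians were -0.51 for S phase and -0.54 for mitosis, and 35 and 29 genes fell. The mitosis count was 0 without DTA-1 replicate 2 and 16 without DTA-1 replicate 3, with medians of -0.82 and -0.86, and the S phase count stayed between 35 and 40 with each library left out.

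**Figure D3:**
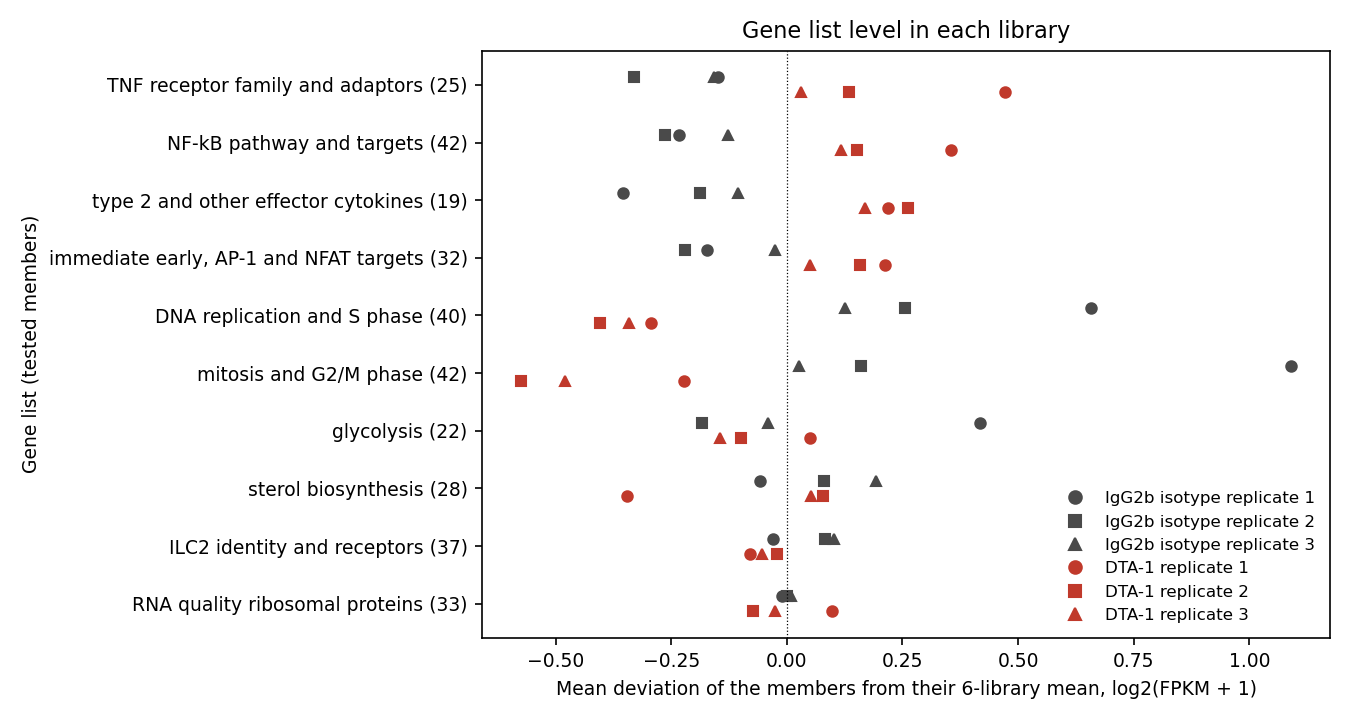
Mean deviation of the tested members of 10 gene lists from their mean over the 6 libraries, on the log2(FPKM + 1) scale; each point is a library (grey, IgG2b isotype; red, DTA-1; the marker shape is the replicate). S phase genes lie at 0.66, 0.26 and 0.13 in the isotype libraries and between -0.40 and -0.29 in the DTA-1 libraries, and isotype replicate 1 also stands highest for mitosis (1.09) and glycolysis (0.42).

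The remaining lists past the camera threshold had median log2 fold changes between -0.46 and 0.27. Targets of p53 lay higher (24 tested, median log2 fold change 0.15, adjusted p = 0.0058; adjusted p = 0.338 with an estimated correlation), with Cdkn1a as their single gene past the test adjusted over the list alone. Tissue repair and extracellular matrix genes lay higher (16 tested, median 0.27, adjusted p = 0.0243; adjusted p = 0.572 with an estimated correlation), and 2 of them rose: Anxa2, which encodes a membrane-binding annexin, from 117 ± 7.46 to 174.5 ± 3.84 FPKM, and the metalloprotease gene Adam8 from 155 ± 24.8 to 258 ± 18.5 FPKM. Genes of ribosome biogenesis and Myc targets lay higher by a median of 0.09 (29 tested, adjusted p = 0.0246; adjusted p = 0.299 with an estimated correlation), with no single member past the test adjusted over the list alone. Myc, a member of both, passed among immediate early genes but not here (adjusted p = 0.0880 over this list alone). Amino acid and ATF4 targets lay higher by 0.08 (33 tested, adjusted p = 0.0420; adjusted p = 0.572 with an estimated correlation), with Atf3 as the single riser; 1 member fell without isotype replicate 2. Sterol biosynthesis genes lay lower by a median of -0.14 (28 tested, adjusted p = 0.0246; adjusted p = 0.700 with an estimated correlation), without a member past the test. DTA-1 replicate 1 alone stood low for sterol genes, at -0.34 from the mean of all libraries on the log2 scale against 0.078 and 0.052 in DTA-1 replicates 2 and 3, and without it the median was -0.0027. Replication-dependent histone genes, fixed as a sign of RNA quality because most of their transcripts lack a poly(A) tail, lay lower (17 tested, median -0.46, adjusted p = 0.0386; adjusted p = 0.572 with an estimated correlation), yet Hist1h1c and Hist1h2bc rose while Hist1h3c and Hist1h2ak fell. Isotype replicate 1 stood highest for these histone genes (0.42 above the mean of all libraries) and for S phase genes (0.66). A fall together with the S phase genes was therefore not told apart from a difference in RNA quality. The count of tissue repair risers was 6, and 1 member fell, without isotype replicate 2, and the p53 count was 0 without any one library except DTA-1 replicate 3. Some of these camera calls were lost when 1 library was left out, in several cases with a median about as large. The sterol call was lost without isotype replicate 3 (median -0.079) or DTA-1 replicate 1, and the ATF4 call without isotype replicate 1, isotype replicate 2 or DTA-1 replicate 1 (medians 0.12, 0.087 and 0.050). The sterol median was -0.28 without isotype replicate 1 and the ATF4 median 0.15 without DTA-1 replicate 3, with both calls kept. The ribosome biogenesis call was lost without isotype replicate 1, isotype replicate 3 or DTA-1 replicate 3 (0.049, 0.11 and 0.052), and the tissue repair call without isotype replicate 1 or DTA-1 replicate 2 (0.10 and 0.25). The histone call was lost without isotype replicate 1, isotype replicate 3, DTA-1 replicate 1 or DTA-1 replicate 3 (-0.24, -0.39, -0.42 and -0.27). The tissue repair, ATF4 and histone calls were also lost once the GC and length trend was removed, with medians of 0.25, 0.065 and -0.25, and the histone call with a minimum mean of 5 FPKM (-0.35). The sterol and ATF4 calls were lost with library quality weights (-0.10 and 0.047) and with isotype replicate 2 and DTA-1 replicate 1 left out together (0.043 and 0.045).

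Tested one by one over all 10501 genes, 3 genes were higher and 1 was lower with DTA-1 (limma, adjusted p under 0.05). Atf3, a stress-induced transcription factor gene on chromosome 1 (191170296 to 191218039), rose from 10.6 ± 1.22 to 29.2 ± 2.07 FPKM, a log2 fold change of 1.38 ± 0.12 (limma adjusted p = 0.0116). Cd200, which encodes a surface glycoprotein that restrains myeloid cells and lies on chromosome 16 (45382135 to 45409053), rose from 4.55 ± 0.424 to 14.4 ± 2.66 FPKM, a log2 fold change of 1.46 ± 0.15 (limma adjusted p = 0.0239). Both lay above every isotype library in each DTA-1 library. The other calls were small nucleolar RNAs, whose short transcripts FPKM measures poorly. Snora69, on chromosome X at 37082912 to 37083042 within Rpl39, was listed at 0 in each isotype library and at 43.7, 24.8 and 24.5 FPKM in DTA-1 replicates 1, 2 and 3. Snora15, on chromosome 5 at 129794546 to 129794676 within Cct6a, was listed at 179, 96.0 and 71.2 FPKM in isotype replicates 1, 2 and 3 and at 0 in each DTA-1 library.

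At an unadjusted p under 0.05, 653 genes were higher and 812 lower, where chance alone gives 525 in all on average, with a wider spread where genes vary together. The groups did not overlap for 21.6% of the tested genes (1171 higher and 1099 lower with DTA-1), where chance gives 10%. Atf3 was the single member of the 26 pathway lists past the threshold over all genes. The Atf3 call was lost without isotype replicate 3 and without each DTA-1 library in turn, and the Cd200 call without any one library, with log2 fold changes of 1.30 to 1.45 and 1.32 to 1.54. The count of higher genes was 1 without isotype replicate 3, without DTA-1 replicate 2 and without DTA-1 replicate 3, and 3 genes were higher and 2 lower when the libraries were scaled to equal totals.

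Few single genes of the ILC2 program passed the test. Of 37 tested identity and receptor genes, 1 fell adjusted over the list alone: Ets1, a transcription factor gene, from 87.5 ± 14.2 to 49.7 ± 4.93 FPKM. The camera test of this list did not pass, but it asks for a shared direction, and 18 members lay above 0 and 19 below. By limma's fry test, which counts changes in either direction, the list passed (adjusted p = 0.0391). The groups did not overlap for 4 higher and 6 lower members, against 21.6% of all tested genes. Gata3, the master regulator of type 2 lymphocytes, measured 165 ± 47.1 and 179 ± 13.5 FPKM. Il1rl1, which encodes the interleukin 33 receptor, measured 253 ± 53.2 and 182 ± 9.05 FPKM, without overlap between the groups. Il2ra measured 1425 ± 251 and 1216 ± 122 FPKM, and Icos 154 ± 67.4 and 85.4 ± 13.4 FPKM. The maturation marker Klrg1 measured 97.2 ± 17.6 and 34.1 ± 20.5 FPKM, without overlap between the groups, and Cd44 149 ± 18.4 and 206 ± 9.92 FPKM, also without overlap. Neither these nor Il1rl1 passed. Without DTA-1 replicate 2 no identity gene fell, without DTA-1 replicate 3 there were 2 and without isotype replicate 1 there were 3, while 1 rose without isotype replicate 2.

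Markers of other cell types were mostly absent or low. Of 142 marker genes from 12 cell types in the files, 23 reached 1 FPKM in at least 3 libraries, and no type had the 5 tested members that the list test needed. Adjusted over each list alone, Ccr3, an eosinophil marker, was lower with DTA-1 (1.86 ± 0.0351 and 0.626 ± 0.395 FPKM), as were Epcam and Cd28, and Gsn was higher (44.7 ± 6.85 and 67.6 ± 15.8 FPKM). The eosinophil list had 1 tested member, so its p was in effect not adjusted, and the lists of Epcam, Cd28 and Gsn had 2, 4 and 2. Over all genes the limma adjusted p of Ccr3, Epcam, Cd28 and Gsn was 0.131, 0.101, 0.108 and 0.223, so none passed. The most abundant marker of each other list did not pass: Lat for T cells (24.6 ± 5.30 and 23.7 ± 1.93 FPKM), Cd79b for B cells (4.66 ± 2.12 and 4.32 ± 1.88), Itga2 for NK cells (1.13 ± 0.0923 and 0.987 ± 0.328), Ccr2 for monocytes (88.5 ± 23.6 and 47.6 ± 29.3), Cst3 for dendritic cells (129 ± 17.4 and 131 ± 16.4), Il3ra for mast cells and basophils (18.4 ± 1.69 and 14.97 ± 1.63), Hopx for epithelium (3.97 ± 0.869 and 3.19 ± 0.530) and Pecam1 for endothelium (35.9 ± 6.90 and 26.9 ± 10.2). Cxcr2 of neutrophils and Hba-a1 of red cells were below 1 FPKM on average in both groups and were not tested. Every tested marker of T cells (4), B cells (4), macrophages (2), epithelium (2) and endothelium (2) had a log2 fold change below 0. So had the 1 tested marker each of NK cells, mast cells and eosinophils. The 2 tested fibroblast markers and 3 of 4 dendritic cell markers lay above 0. Whether the make-up of the cultures differed was not tested. Ribosomal protein genes showed a median log2 fold change of 0.00 over 33 tested genes, with Rpl41 at 5693 ± 498 and 5974 ± 197 FPKM.

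Libraries also differed in ways that the groups did not explain. Isotype replicate 3 lay closer to DTA-1 replicates 2 and 3, at 7.83 and 10.3 times the counting noise, than to isotype replicates 1 and 2, at 16.4 and 26.8 times. Isotype replicate 2 deviated from the other libraries with transcript GC content, with a Spearman correlation across genes of -0.59 between deviation and GC content. The correlations of the other libraries lay between -0.23 and 0.36, and genes are not independent replicates. Small RNA names took between 0.0705% and 5.19% of the FPKM of a library, with both extremes in a replicate 2, of the isotype and of DTA-1.

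**Figure D4:**
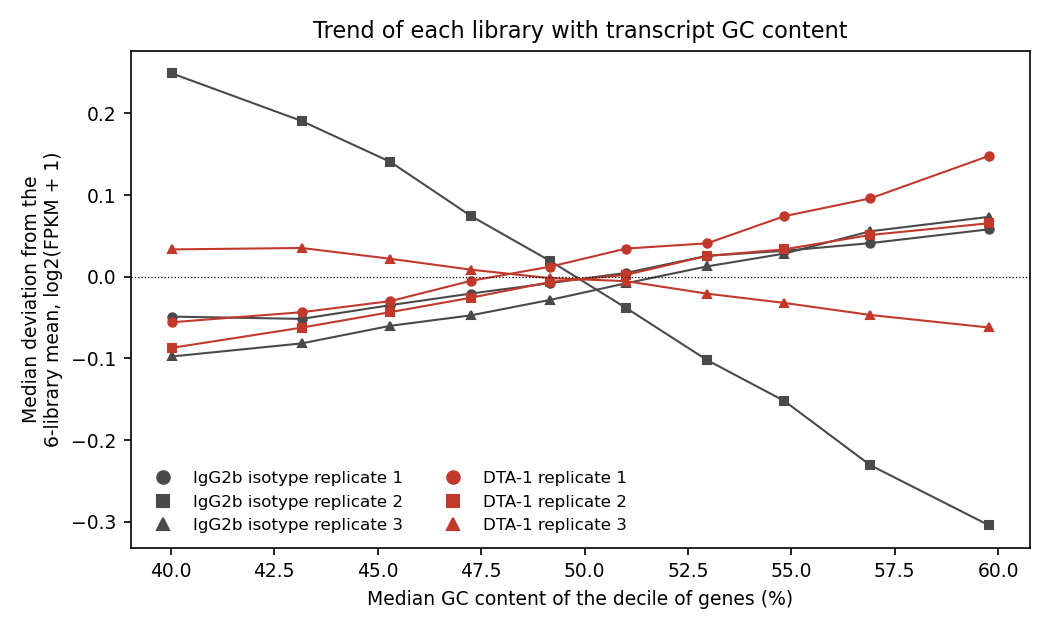
Median deviation of genes from their mean over the 6 libraries on the log2(FPKM + 1) scale, against the median GC content of 10 equal groups of genes; each line is a library (grey, IgG2b isotype; red, DTA-1; the marker shape is the replicate). Isotype replicate 2 falls from 0.25 in the group with the lowest GC content to -0.30 in the group with the highest, while the other libraries stay between -0.10 and 0.15.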

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

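The settings with a GC and length trend removed, quantile normalization, library quality weights, an adjusted p under 0.10, small RNA names left out, and isotype replicate 2 and DTA-1 replicate 1 left out together (4 libraries) were chosen after seeing the data. The planned negative binomial tests, voom and the count-based filter were not run because the values are not counts. Depth limits low genes, as does the pseudocount of 1 FPKM.

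Against 3 genes higher and 1 lower, 1 was higher with no filter beyond a value above 0 and 1 at an adjusted p under 0.01, and 2 were higher when tested against a minimum fold change. Equal library totals gave 3 higher and 2 lower, quantile normalization 5 and 2, and the 4 libraries 5 and 2. An adjusted p under 0.10 gave 44 and 45, and library quality weights 161 and 314, with weights from 0.263 for isotype replicate 2 to 5.95 for DTA-1 replicate 2. None was lower once the GC and length trend was removed (2 higher) or small RNA names were left out (2 higher), where 653 and 812 genes had been higher and lower at an unadjusted p under 0.05 in limma; the second setting removes the small nucleolar RNAs by construction, and the cause was not tested for the other settings. Leaving out each library gave 1 to 3 higher and 1 lower, with fewer samples. Of the 27 lists, 12 passed, 8 to 12 did with each library left out, and 0 with an estimated correlation or by fry's directional test. By fry's test in either direction 12 passed, but these were partly other lists. ILC2 identity genes and chemokines passed it, for example, and mitosis genes did not.

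Whether replicate numbers paired the samples stayed open. Correlations of deviations from the group means were 0.39, -0.10 and -0.13 for numbers 1, 2 and 3. Isotype replicates 2 and 3 correlated best with DTA-1 replicates 3 and 2 (0.49 and 0.38). Trends of single libraries, such as that with GC content, also enter these deviations, so the check cannot decide on pairing. The replicate block gave 59 higher and 126 lower genes and 10 lists, with the ribosome biogenesis and ATF4 calls lost. A block of the library-name number gave 60 and 76 genes. Some of these numbers occurred in a single group, and such libraries add nothing to the comparison within blocks. That block therefore rests on fewer libraries and leaves little room to measure the spread.

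The median of all genes stayed between -0.02 and 0.02 in every setting. Of the log2 fold changes of named genes under other settings, 1616 kept their direction and side of the threshold, 76 came to pass, 15 no longer passed and 26 changed sign, none of them past the threshold. With the 4 libraries these were Tnfrsf18 (-0.082), Il4 (0.023), Lat (0.0075), Itga2 (0.054) and Cst3 (-0.19). With library quality weights they were Il4 (0.13), Itga2 (0.025), Cst3 (-0.13) and Rpl41 (-0.039), the last also with quantile normalization (-0.12). With the library-name block they were Gata3 (-0.13), Il2ra (0.0065), Nfkb1 (-0.044), Itga2 (0.038) and Cst3 (-0.032). Cst3 also turned with equal library totals (-0.0058) and with the GC and length trend removed (-0.024). With each library left out, Il4 ranged from -0.31 to 0.028, Gata3 from -0.072 to 0.35, Lat from -0.16 to 0.13, Cd79b from -0.35 to 0.21, Itga2 from -0.20 to 0.028 and Cst3 from -0.087 to 0.10.

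Of the list tests, 361 kept their direction and side, 49 no longer passed, 5 came to pass and 17 turned direction. Among those that came to pass by camera, glycolysis genes lay lower without isotype replicate 2 (median -0.24, adjusted p = 0.0027) and without DTA-1 replicate 1 (-0.16, adjusted p = 0.0393). They also passed as lower with the 4 libraries (-0.27, camera adjusted p = 8.9e-04). The camera direction turned for chemokines, whose medians were -0.048 with median-of-ratios scaling, -0.049 by fry, -0.054 with the GC and length trend removed, -0.027 with quantile normalization and 0.0034 with the 4 libraries. It also turned for ribosomal proteins with the replicate block and by fry (both -0.0047). With single libraries left out it turned in 7 lists, whose medians ranged from 0.013 to 0.33 for regulatory genes, -0.12 to 0.028 for chemokines, -0.24 to 0.012 for glycolysis, -0.15 to 0.016 for hypoxia targets, -0.014 to 0.085 for autophagy, 0.0044 to 0.14 for antigen presentation and -0.026 to 0.030 for ribosomal proteins. The cause of these turns was not tested.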

Other observations

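Co-inhibitory genes moved in both directions. Of 19 tested regulatory and co-inhibitory genes, 2 rose and 2 fell adjusted over the list alone in limma. Tigit, an inhibitory receptor gene, fell from 43.3 ± 4.07 to 22.0 ± 5.54 FPKM, and Ctla4, another inhibitory receptor gene, from 29.2 ± 4.32 to 8.78 ± 5.52 FPKM. The genes of the PD-1 ligands rose, Pdcd1lg2 from 5.40 ± 0.306 to 9.52 ± 2.32 FPKM and Cd274 from 6.56 ± 0.571 to 9.90 ± 1.196 FPKM. The median log2 fold change of this list was 0.35 and its mean 0.01. Without isotype replicate 3 none of these genes passed, without isotype replicate 2 there were 4 risers, and without DTA-1 replicate 1 or 2 there was 1 riser. Of 22 chemokine and chemokine receptor genes, 6 rose and 5 fell. The risers encode chemokines, among them Ccl3, from 2.04 ± 1.51 to 8.34 ± 2.93 FPKM, and Ccl1, from 0.167 ± 0.158 to 2.30 ± 1.63 FPKM. The genes that fell encode receptors and a homing integrin: Ccr1, Ccr3, Cxcr4, S1pr1 and Itgb7. Without isotype replicate 1 there were 3 risers and 2 that fell, and without isotype replicate 2 there were 3 that fell. Neither list passed camera.

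Among 24 cytokine receptor signalling and STAT5 target genes, Stat5a rose from 43.6 ± 4.73 to 75.0 ± 13.0 FPKM, Ccnd2 and Lta also rose, and Gzmb and Ikzf3 fell. The fall was seen in 1 gene without isotype replicate 1 or isotype replicate 3. In the type 1 and cytotoxic list of 7 genes, Gzmb fell from 3.53 ± 0.751 to 1.06 ± 0.766 FPKM, and Ccl5 and Il12rb1 rose. No gene of that list rose without isotype replicate 2, DTA-1 replicate 1 or DTA-1 replicate 2, 1 rose without isotype replicate 1, and Gzmb did not pass without isotype replicate 2. Batf and Maf fell among 4 tested type 3 genes. Of 17 hypoxia targets, P4ha2 rose from 6.20 ± 0.401 to 15.5 ± 5.02 FPKM and Bnip3 fell, the latter not without DTA-1 replicate 2 or 3, while 2 fell without isotype replicate 2. No member passed adjusted over the list alone among apoptosis and survival (26 tested, among them Bcl2l1, Birc3 and Cflar, which passed in the NF-kB list), glycolysis (22), oxidative phosphorylation (34), fatty acid (24), unfolded protein response (26), interferon-stimulated (20), autophagy and lysosome (28) and antigen presentation genes (19). Their smallest limma p values belonged to genes such as Pkm (1207 ± 92.7 and 923 ± 6.25 FPKM) and Cd80 (17.7 ± 3.04 and 26.4 ± 1.45 FPKM). With 1 library left out, single members of 4 of these lists passed: 1 apoptosis gene rose without isotype replicate 2 and without isotype replicate 3, 1 fatty acid gene rose and 1 fell without isotype replicate 2, 1 unfolded protein response gene rose without isotype replicate 3, and 1 autophagy gene fell without DTA-1 replicate 3.

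Of the tests that follow, those of GC content for the cell-cycle genes and of small RNA values were chosen only after the result was seen. The 82 tested S phase and mitosis genes had a median log2 fold change of -0.77 with DTA-1. A scaling offset shared by all genes is argued against by the median log2 fold change of 0.014 over all tested genes. The 3 other scalings therefore had little to correct, and the median of the cell-cycle genes stayed at -0.77 or lower under them. That median was also -0.77 once the trend with GC content and length was removed, which argues against that trend as its source. No single library accounts for the whole of the lower median, which lay between -0.93 and -0.51 with each library left out. Cells of another type would bring their abundant transcripts, but Cd3e, the highest of 10 such markers in the DTA-1 libraries, averaged 0.715 FPKM. Some members of the fixed marker lists stood higher, such as Cst3 (129 FPKM with the isotype and 131 with DTA-1) and Gsn (44.7 and 67.6 FPKM). The values therefore argue only against cells that carry the 10 markers. The share of dividing cells was not measured, and what lowered these transcripts, a difference between the cultures included, stays open.

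DTA-1 replicate 1 stood apart, with Il9 at 2.80 times the mean of the other DTA-1 libraries. The ratio was 2.95 once the trend with GC content and length was removed, which argues against that trend as its source. A larger response in that library was also considered. If it were the source, differences of replicate 1 from another DTA-1 library would follow the response measured in the third. The correlations across genes were -0.083 and 0.096. Both lay under the limit set beforehand for arguing against a larger response, the second only just. They did not bear out a larger response of the same kind, and the narrow margin does not exclude one. What set this library apart stays open.

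The small nucleolar RNAs among the called genes may reflect values at the edge of estimation. Of 35 small RNA names that reached 5 FPKM in a library, 29 were at 0 in another, against 8 of 8660 other genes, a ratio of shares of 897. Their host genes did not move with them: the log2 fold change of Cct6a was 0.050 and that of Rpl39 was -0.085. A change in the small RNAs themselves is not excluded.

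The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. In 1 of these, the real one, 4 genes passed, and the highest count of the others was 1 gene. For the lists the real split gave 12, again in 1 of 10 splits, and the highest of the others gave 9, and none of the 12 passed with an estimated correlation. At an unadjusted p under 0.05 the real split gave 1465 genes and the highest of the others 723. Each of the other splits mixes isotype and DTA-1 libraries, so a real difference widens their spread and they do not show chance alone.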
